A study of Mus musculus with 2 samples.

How the data were processed

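RNA was measured in single muscle stem cells of mouse, the resident stem cells of skeletal muscle. Per the labels, cells were sorted by FACS into 384-well plates, and polyadenylated RNA was copied and tagged in each well with a modified CEL-Seq2 protocol, in which a barcode marks the well and a short random tag (UMI) marks each copied molecule. The UMI took bases 1 to 6 of the first read and the barcode bases 7 to 14. Plate 1 held freshly isolated cells, called quiescent in the labels, and cells grown for 96 h in medium with 25 mM glucose (high glucose). Plate 2 held cells grown for 96 h with 5 mM glucose (low glucose) or 10 mM galactose. The media also held 1 mM pyruvate, serum, chick embryo extract and bFGF.

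The deposited tables gave raw counts per gene and well with no normalization, which was checked on the values: all were whole numbers, totals differed between wells, and the highest count of 1 gene in 1 well was 1564, under the 4096 tags that 6 bases allow. Whether the counts were collapsed by UMI, and the aligner, the counter, the genome build and the annotation, are not given in the sources used here. The submitters' processing notes name edgeR without a version or a role. The condition of each of the 457 wells came from the deposited well sheet, never from the values.

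Wells were kept with at least 500 gene counts and 250 detected genes. This left 456 wells and dropped 1 high glucose well with 8 counts. ERCC spike-ins, synthetic RNAs added in equal amount to each well, were left out of the totals and used for the ratio of gene to spike-in counts, for 1 alternative scaling and for the spread of spike-in species between pools. Of 21216 gene identifiers, 21132 (99.6%) received a symbol from the mouse GENCODE annotation, release M21. The others held 0.211% of counts and stayed in the totals. No doublet caller was run. The marker lists fixed for other cell types were used to look for wells of another type, defined as 3 or more markers of the same type in a well.

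Counts were summed over the kept wells of a condition into a pool and scaled by its total gene counts to CPM. Each comparison is the ratio of the CPM of 2 pools with its exact conditional (Clopper-Pearson) 95% interval, and intervals of a CPM are exact Poisson. All intervals cover counting error only. They were not adjusted for picking genes by their interval, so 95% coverage does not hold for genes named that way. There was 1 library per condition and cells are not replicates, so there was no replicate check, and no test between conditions was run. Log2 ratios used a pseudocount of 1 CPM. Numbers of genes whose pool ratio was at least 2 were counted among genes with a mean CPM of the 2 pools of at least 50. List medians used members with a mean CPM of at least 10, called measured below, and a member was called higher or lower when its ratio was at least 1.5 and its interval left out 1. The 95% interval of a list median came from 500 Poisson draws of the counts. Each list median was also placed among those of 10000 random lists of the same size, drawn within 50 ranks of mean CPM of each member, and this percentile describes these libraries only. For a gene with 0 counts, folds use a floor of 3 counts, and none is given when both pools lie at or under it. Shares of cells with a count were taken after thinning every cell to 1000 counts, with shallower cells left out, and carry exact binomial 95% intervals.

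The lists, the comparisons, the genes to name and 11 of the alternative settings were fixed before the data were examined. The genes named were the 10 higher and 10 lower genes per comparison, at a mean CPM of at least 50 and in at least 5% of cells of the higher pool, whose interval bound nearest 1 lay farthest from 1. To these came up to 4 members of each list (the 2 with the most counts and the 2 with the bound farthest from 1) and a fixed set from Pax7 to Galk1 that was always looked up. Some genes the rule named were left out of the text and the plots. The 37 lists named 707 genes, of which 632 could be looked up here. Myog and Mki67 were not analysed here.

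The alternatives were TMM factors, median-of-ratios factors, equal weight per cell, a minimum of 2000 counts per well, no minimum, the other expression minimum (10 CPM for numbers of genes and 50 CPM for lists), mitochondrial genes out of the total, a correction for the number of UMIs, leaving out wells with markers of another cell type, thinning, and a pseudocount of 10 CPM. Scaling by the summed spike-in counts and a total over protein-coding genes were added after the data were seen. Shares were also taken after thinning to 500 and 2000 counts and without thinning.

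The steps were tested on simulated data, in which pool counts were Poisson draws and 200 genes were given known folds. The simulation held no variation between cells, plate rows or libraries. Coverage of the intervals near 95% thus followed by construction and does not cover such variation. Intervals held the true ratio for 95.6% of genes in the comparison of high glucose with freshly isolated cells and for 95.3% in galactose against low glucose. In the former, the median recovered fold was 2.01 for true 2-fold and 4.09 for true 4-fold differences, and 25 of 3648 genes without a difference reached a ratio of 2. Of 100 simulated lists of 15 genes without a shift, 8 and 3 fell outside the central 95% of random lists in these comparisons. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9, with R 4.3.3, edgeR 4.0.16 for TMM and DESeq2 1.42.0 for the median of ratios.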

Results

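The data hold 456 single mouse muscle stem cells in 4 conditions: 102 freshly isolated cells, 113 cells grown in high glucose, 120 in low glucose and 121 in galactose. The median gene counts per cell were 2536 (range 1549 to 6750) in freshly isolated cells and 6747 (868 to 18844) in high glucose. They were 13371 (2616 to 39631) in low glucose and 14496 (1711 to 44097) in galactose. The summed counts behind each pool were 284109, 887611, 1734279 and 2035682 in the same order. Freshly isolated and high glucose cells shared plate 1, and low glucose and galactose cells shared plate 2. Each condition filled its own 6 plate rows, so row position and condition were confounded. Comparisons across plates were also confounded with the plate.

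Cells grown in culture held more RNA relative to the spike-ins than freshly isolated cells. The median ratio of gene counts to spike-in counts was 18.3 in freshly isolated cells and 57.0 in high glucose, a ratio of 3.10 within plate 1. It was 47.7 in low glucose and 47.8 in galactose, a ratio of 1.00 within plate 2. Medians of single plate rows ran from 15.3 to 22.6 for freshly isolated cells and from 47.7 to 65.8 for high glucose cells, without overlap.

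**Figure D1:**
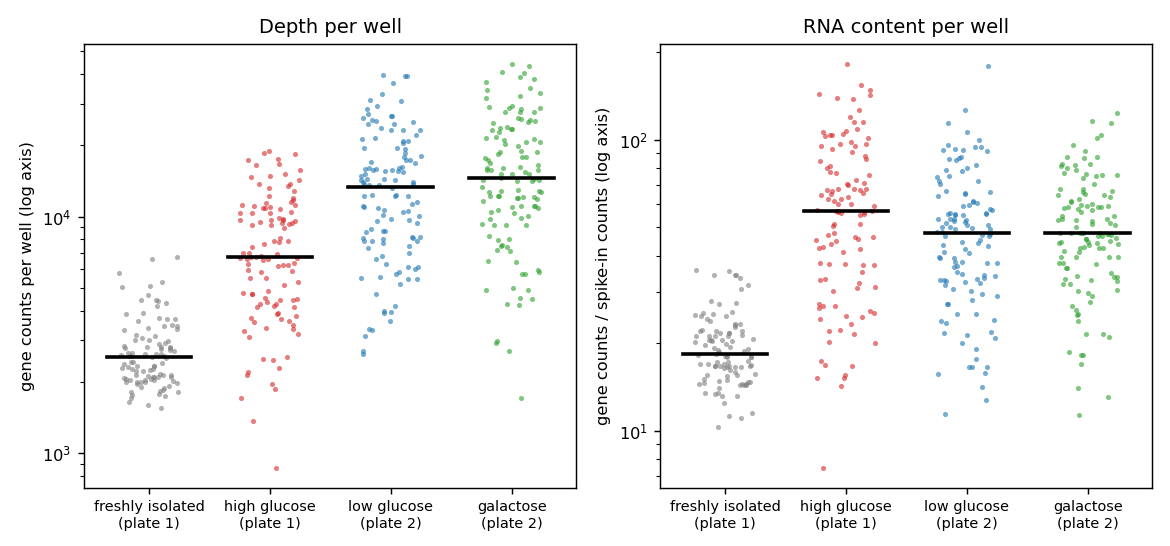
Gene counts per well (left) and gene counts over spike-in counts per well (right) on log axes, with 1 point per kept well and the median of each condition as a bar. The median ratio to spike-ins was 18.3 in freshly isolated cells and 47.7 to 57.0 in the cultured cells.

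Muscle stem cells leave quiescence when they are isolated and grown, and the comparison of high glucose with freshly isolated cells, within plate 1, addresses the change with 96 h of culture, though each condition filled its own plate rows. Vcam1, a surface marker of quiescent muscle stem cells, was lower in high glucose, at 48.4 against 465 CPM (ratio 0.104, 95% interval 0.0721 to 0.148). Pax7, the transcription factor that marks these cells, was lower at 56.3 against 119.7 CPM (ratio 0.471, 0.298 to 0.751). Spry1, an inhibitor of growth factor signalling linked to quiescence, was lower at 128 against 408 CPM (ratio 0.315, 0.241 to 0.411). Per 1000 spike-in counts Vcam1 was still lower (2.92 against 9.12), Spry1 stood at 7.74 against 8.01, and Pax7 was higher in high glucose (3.39 against 2.35). Cd34, another marker of quiescent cells, went the other way, with 281 against 134 CPM (ratio 2.10, 1.49 to 3.03). Of 17 measured quiescence markers, 15 were lower in CPM, 1 was higher and 1 was neither, with a median log2 ratio of -2.26. Among them were Sdc4 with 436 against 2094 CPM and Chrdl2 with 10.1 against 208 CPM. Per spike-in count, only 3 of the 17 had an interval wholly below the range of 1.5-fold around 1. The intervals of 2 lay above this range and those of 12 reached it.

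Genes induced by stress or dissociation were also lower in CPM in high glucose. Hspa1b, a heat shock protein, had 767 against 5695 CPM, and Hspa1a had 288 against 3499 CPM. Nr4a1, an immediate early transcription factor, had 18.0 against 345 CPM. Of 28 measured members of the immediate early and dissociation list, 23 were lower, none was higher and 5 were neither, with a median log2 ratio of -1.78. Hspa5, a chaperone of the unfolded protein response, had 789 against 3879 CPM, and 8 of 14 members of that list were lower, 1 was higher and 5 were neither (median -0.74). Ndrg1, of the hypoxia list, had 288 against 1077 CPM, and 4 of 11 members were lower and 7 were neither (median -0.43).

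Myod1, the myogenic factor that marks activated cells and myoblasts, was lower in CPM in high glucose, at 705 against 2446 CPM (ratio 0.288, 0.258 to 0.322). Per 1000 spike-in counts its level was 42.5 in high glucose and 48.0 in freshly isolated cells. Myf5 had 286 against 394 CPM (ratio 0.726, 0.579 to 0.915), but 17.2 against 7.74 per 1000 spike-in counts. Of 12 measured myoblast markers, 8 were lower and 4 were neither (median log2 ratio -1.29), and Igfbp5 had 25.9 against 440.0 CPM. The differentiation list had 5 measured members, all neither (median 0.32). Notch3, of the Notch list and also of the smooth muscle and pericyte list, had 19.2 against 204 CPM, with 4 of 7 members lower and 3 neither (median -1.61). Col3a1, a fibrillar collagen, had 126 against 873 CPM, and 11 of 15 collagens and matrix genes were lower and 4 were neither (median -1.85). H2-K1, of the interferon list, had 214 against 616 CPM, with 3 of 5 members lower and 2 neither (median -1.11).

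Genes of mitochondrial respiration encoded in the nucleus were higher in high glucose. Cyc1, a cytochrome of complex III, had 206 against 45.8 CPM (ratio 4.51, 2.57 to 8.62), and Uqcrc2 had 225 against 63.4 CPM (ratio 3.56, 2.19 to 6.12). Of 57 measured members of the nuclear-encoded oxidative phosphorylation list, 30 were higher, 1 was lower and 26 were neither (median log2 ratio 0.95). Transcripts of the mitochondrial genome were lower in CPM, with 10 of 11 members lower and 1 neither (median -1.38), and mt-Cytb had 2419 against 6297 CPM. Pgd and Tkt of the pentose phosphate pathway had ratios of 2.33 (1.33 to 4.42) and 2.93 (1.27 to 8.34), with 3 of 6 members higher and 3 neither (median 1.01). The TCA cycle list had 5 of 15 members higher and 10 neither (median 0.54). Ribosomal protein genes had 32 of 78 members higher, 2 lower and 44 neither (median 0.47), such as Rps2 with 2838 against 1014 CPM.

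Glycolysis genes moved both ways. Pgk1 had 442 against 119.7 CPM (ratio 3.69, 2.60 to 5.41), whereas Pkm had 2872 against 2647 CPM and Ldha 377 against 412 CPM. Slc16a3, a lactate exporter, had 1 count in high glucose and 19 in freshly isolated cells (ratio 0.0168, 0.000405 to 0.106). The list had 3 of 14 members higher, 2 lower and 9 neither (median 0.27). Pdk4, which blocks pyruvate dehydrogenase, had 159 against 296 CPM (ratio 0.537, 0.407 to 0.713), and the pyruvate entry list had 1 of 10 members higher, 2 lower and 7 neither (median 0.33). Acly, which makes acetyl-CoA for histone acetylation, had 59.7 against 35.2 CPM, with an interval of the ratio from 0.854 to 3.74. The acetyl-CoA list had 2 of 4 members lower and 2 neither (median -1.08). Kat2a, a histone acetyltransferase, had a ratio of 3.04 (1.47 to 7.30) and Ncoa1 a ratio of 0.299 (0.193 to 0.464), and that list had 3 of 12 members higher, 1 lower and 8 neither (median 0.49). Sirt1 had 125 against 144 CPM (ratio 0.867, 0.601 to 1.27), and the list of deacetylases and sirtuins had 2 of 8 members lower and 6 neither (median -0.39). Ugp2, of the Leloir pathway that breaks down galactose, had 39.4 against 119.7 CPM, with 2 of 3 members lower and 1 neither (median -1.50). The member called neither was Galk1, with 18 counts against 1 (ratio 5.76, 0.910 to 240).

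Mdm2, a target of p53, had 1507 against 440.0 CPM (ratio 3.43, 2.85 to 4.15) and Bax 217 against 35.2 CPM (ratio 6.18, 3.29 to 13.1). The p53 and cell cycle inhibitor list had 7 of 15 members higher, 2 lower and 6 neither (median log2 ratio 0.63), while Cdkn1a stood at 1983 against 2168 CPM. Ccnd1, a cyclin of cell cycle entry, had 98.0 against 70.4 CPM, with an interval of the ratio from 0.849 to 2.39. The S phase list had 2 of 15 members higher and 13 neither (median 0.71), and the G2/M list 1 of 7 higher and 6 neither (median 0.66), as with Gtse1 at 145 against 91.5 CPM. Asns and Ddit3, of the integrated stress response, had ratios of 4.88 (1.81 to 18.5) and 3.72 (1.81 to 8.87), with 3 of 18 members higher, 2 lower and 13 neither (median -0.21). Medians were -0.28 for fatty acid oxidation (0.080 when cells were thinned), -0.61 for fatty acid synthesis, 0.20 for cholesterol synthesis and -0.04 for autophagy and lysosome. Means differed in sign from medians for glycolysis (-0.03), fatty acid oxidation (0.04), the integrated stress response (0.07) and cholesterol synthesis (-0.03). Txnip, the measured member of the MondoA list, had 84.5 against 95.03 CPM.

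Over all genes, 689 of 3848 had a pool ratio of at least 2 in favour of high glucose and 472 in favour of freshly isolated cells, so that 59.3% of both were higher in high glucose. With TMM factors this share was 46.4% and with median-of-ratios factors 43.1%, with shifts of the all-gene median of -0.17 and -0.21 on the log2 scale. Scaling by spike-ins, added after the data were seen, gave 2928 and 63 of the 3455 genes that passed the minimum under it, and moved the median of the 3848 genes by 1.59. With the same members as in CPM, the medians of the myoblast, interferon, unfolded protein, mitochondrially encoded, Leloir, acetyl-CoA, fatty acid oxidation, fatty acid synthesis, autophagy, deacetylase, integrated stress and hypoxia lists were then above 0, as were the log2 ratios of Pax7, Myf5, Cdkn1a, Txnip, Ldha, Slc2a1, Pdk4, Sirt1, H2-K1, Ugp2 and mt-Cytb. The Notch median was -0.025. The medians of the immediate early and collagen lists moved from -1.78 to -0.17 and from -1.85 to -0.26, and that of the quiescence list from -2.26 to -0.68. The protein-coding genes picked by the naming rule as higher were Plin2, a coat protein of lipid droplets (ratio 11.1, 5.79 to 24.6), Tnfrsf11a (127 counts against 2, ratio 20.3, 5.51 to 169.7), Phlda3 (8.78, 5.17 to 16.2) and Ctsd (7.98, 4.60 to 15.1). Lower were Erfe (ratio 0.0363, 0.0266 to 0.0485), Arl4d (0.0512, 0.0379 to 0.0681) and Meg3, a long noncoding RNA (0.0540, 0.0351 to 0.0803). Lsp1 had 1 count against 42 (ratio 0.00762, 0.000189 to 0.0448). Gm6644, Gm12551 and Gm12138, pseudogenes with ratios of 15.2, 19.0 and 9.94, are uncertain, since how reads shared with near-identical copies were counted is not given in the sources used here.

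**Figure D2:**
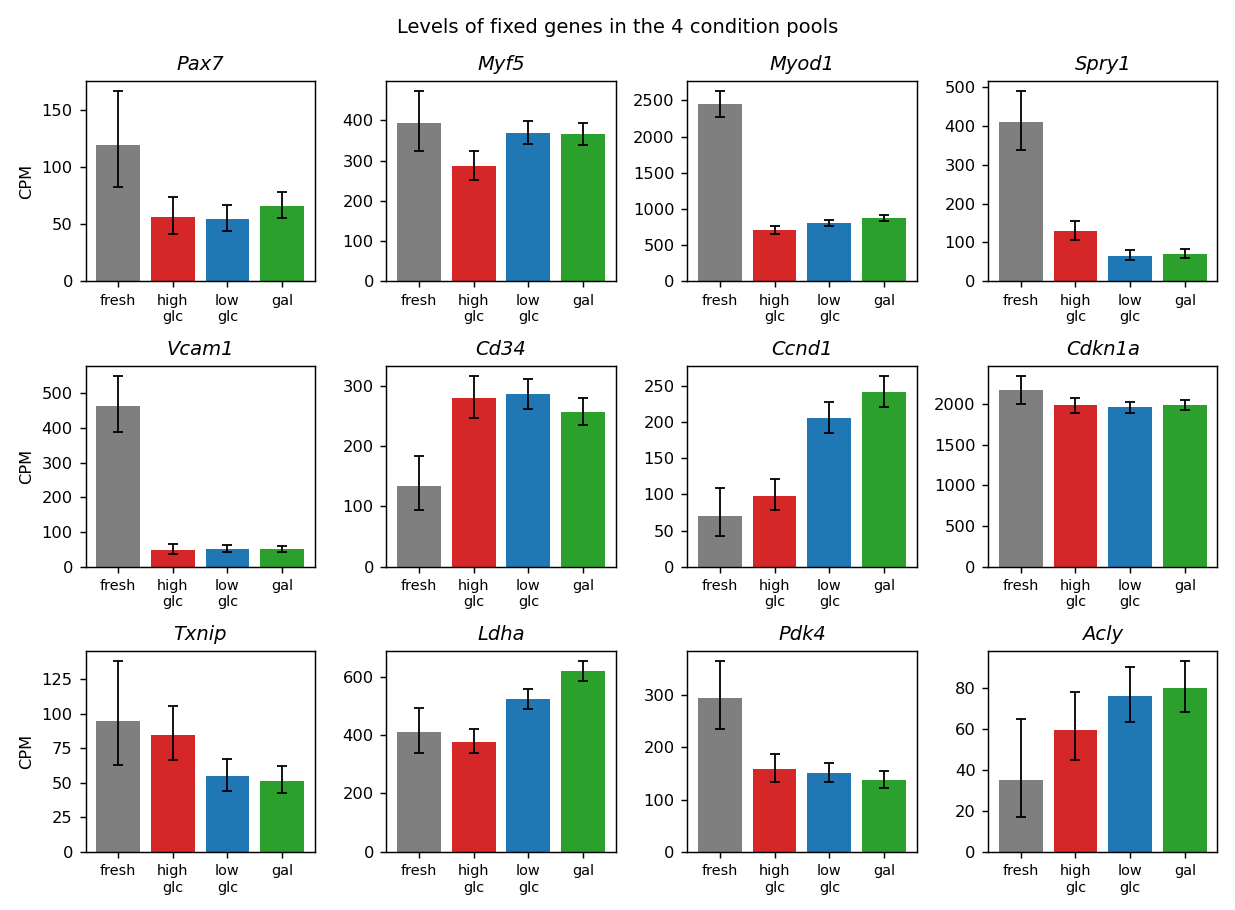
CPM of 12 fixed genes in the pools of freshly isolated, high glucose, low glucose and galactose cells, with exact Poisson 95% intervals that cover counting error only. Vcam1 stood at 465 CPM in freshly isolated cells and between 48.4 and 51.3 CPM in the cultured pools, and Cdkn1a between 1956 and 2168 CPM in all pools.

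Summed CPM of the gene lists for other cell types were mostly higher in freshly isolated cells. Only 2 of 10 immune, 6 of 11 fibro-adipogenic, 3 of 7 glial, 5 of 10 mature myofibre and 2 of 5 tenocyte genes could be looked up. Low sums of these lists therefore do not show that such cells were absent. Summed CPM of the fibro-adipogenic list were 141 in high glucose and 1126 in freshly isolated cells, those of the endothelial list 65.3 and 183, and those of the smooth muscle and pericyte list 231 and 616. Col3a1 made up 873 of the 1126 CPM and Dpt 201 CPM. Col3a1 had a count in 72 freshly isolated wells and in 61.9% of high glucose, 35.8% of low glucose and 36.4% of galactose cells. Acta2, of the smooth muscle and pericyte list, had one in 30 freshly isolated wells and in 57.5%, 41.7% and 48.8% of these cultured cells. Counts of these genes thus do not by themselves show a cell of another type. Dpt had a count in 39 of 102 freshly isolated wells and stood at 4.51 CPM in high glucose. Glial, immune and mature myofibre genes summed to 21.1, 3.52 and 66.9 CPM in freshly isolated cells and 6.76, 6.76 and 28.2 CPM in high glucose. The tenocyte list was listed at 0 CPM in freshly isolated cells and at 6.76 CPM in high glucose. No erythroid gene could be looked up. A well with 3 or more markers of the same other type was seen 1 time in freshly isolated cells (smooth muscle or pericyte) and 1 time in high glucose (endothelial). The immune type could not meet this rule, since only 1 of its markers could be looked up. The fibro-adipogenic and glial types had 3 markers each, so all 3 had to have a count in the same well. On the other plate most of the list sums were lower than in high glucose. They were 39.2 CPM in low glucose and 32.4 in galactose for the fibro-adipogenic list, 6.34 and 4.42 for the endothelial list, and 74.96 and 62.88 for the smooth muscle and pericyte list. The tenocyte sum was higher, at 9.80 and 9.33 CPM, and the immune sum was 2.88 and 8.84 CPM. Plate and medium cannot be separated in these sums.

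After thinning to 1000 counts, Myod1 had a count in 63.7% of freshly isolated cells (53.6 to 73.0) and in 49.1% of high glucose cells (39.5 to 58.7), against 86.3% and 93.8% without thinning. In low glucose and galactose the thinned shares of Myod1 were 52.5% and 50.4%, and without thinning 99.2% of low glucose cells and all 121 galactose cells had a count. Pax7 had a count in 10.8% of freshly isolated, 8.04% of high glucose, 5.00% of low glucose and 3.31% of galactose cells, with intervals that overlapped, against 27.5%, 26.5%, 46.7% and 52.9% without thinning. Spry1 had a count in 21.6%, 9.82%, 6.67% and 8.26% of cells in the same order, against 49.0%, 56.6%, 53.3% and 60.3% without thinning. Thinned shares of Myf5 were 29.4%, 19.6%, 32.5% and 35.5%, and those of Cd34 were 11.8%, 19.6%, 20% and 19.0%. Unthinned shares were 57.8%, 60.2%, 90.8% and 92.6% for Myf5 and 29.4%, 55.8%, 82.5% and 84.3% for Cd34. Ccnb1, a mitotic cyclin, had a count in 1 of 102 freshly isolated cells and in no cell of the other conditions after thinning, with upper limits of 3.24% in high glucose, 3.03% in low glucose and 3.003% in galactose. Without thinning it had a count in 1 of 102 freshly isolated cells (0.980%), 1 of 113 high glucose cells (0.885%), none of 120 low glucose cells and 2 of 121 galactose cells (1.65%). Thinning left out 1 high glucose cell.

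Galactose in place of glucose is used to push cells towards respiration. The comparison of galactose with low glucose, within plate 2, addresses the sugar of the medium, again with each condition in its own plate rows. Ccl2, a chemokine, was higher in galactose, at 348 against 231 CPM (ratio 1.51, 95% interval 1.33 to 1.71). Ifrd2 had 66.3 against 37.5 CPM (ratio 1.77, 1.31 to 2.42), and Sparc, a matrix protein, had 270.2 against 190.3 CPM (ratio 1.42, 1.24 to 1.63). Hmga2, a chromatin protein of growing cells, had 673 against 518 CPM (ratio 1.30, 1.19 to 1.42). Lower in galactose were Akr1b3, the aldose reductase that acts on sugars (518 against 678 CPM, ratio 0.764, 0.702 to 0.830), Trib1 (ratio 0.622, 0.492 to 0.784), Gcc2 (0.577, 0.431 to 0.770) and Ifrd1 (0.639, 0.493 to 0.826). Ftl1-ps1 and the pseudogene Gm12138 had ratios of 0.779 (0.728 to 0.834) and 0.652 (0.552 to 0.770), which are uncertain for the same reason. None of 3997 genes with a mean CPM of at least 50 had a pool ratio of at least 2 in either direction. At a minimum of 10 CPM, 22 genes were higher and 21 lower, and after thinning, which leaves fewer counts, 186 and 186. Beyond counting error the SD of log2 ratios between these pools was 0.0889 for genes and 0.0797 for spike-in species (upper end 0.217). Small ratios between the sugars may therefore be technical. The genes above were picked for the most extreme intervals among the genes compared, which counting error alone can also make extreme.

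Of the hypoxia response list, 2 of 12 members were lower in galactose than in low glucose and 10 were neither. P4ha1, a lower one, had 24.6 against 44.4 CPM (ratio 0.553, 0.380 to 0.800). Short of the 1.5-fold limit were Kdm3a with 46.2 against 69.2 CPM (ratio 0.667, 0.504 to 0.882) and Ndrg1 with 99.7 against 138 CPM (ratio 0.724, 0.597 to 0.876), and Vegfa had 191 against 186 CPM. The median log2 ratio of the list was -0.29 (95% interval -0.49 to -0.06), at percentile 0.020 of random lists. The S phase list had a median of 0.20 (0.03 to 0.36) and the G2/M list one of 0.27, with an interval that included 0 (-0.04 to 0.51). Mcm4, a helicase subunit, had 24.6 against 11.53 CPM (ratio 2.13, 1.25 to 3.78), Mcm7 127 against 97.45 CPM (1.30, 1.07 to 1.59) and Gtse1 197 against 149.9 CPM (1.32, 1.12 to 1.55). Ccnd1 had 242 against 205 CPM (ratio 1.18, 1.03 to 1.36). The S phase list had 1 of 17 members and the G2/M list 1 of 7 members higher, and 16 and 6 were neither. Cholesterol synthesis genes had a median of 0.20, with 1 of 18 higher and 17 neither, as with Msmo1 at a ratio of 1.21 (1.01 to 1.45), but the median was -0.011 when cells were thinned. Ribosomal protein genes had a median of -0.06 with all 79 members neither.

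No measured member of the nuclear-encoded and mitochondrially encoded respiration lists was called higher or lower between the sugars. The nuclear-encoded oxidative phosphorylation list had a median log2 ratio of 0.00 (95% interval -0.06 to 0.05) with all 61 members neither, and Atp5b had 954 against 948 CPM. Some members had intervals that left out 1, such as Ndufa4 with a ratio of 0.785 (0.640 to 0.962) and Ndufc2 with 1.21 (1.02 to 1.45). Medians were 0.06 for mitochondrially encoded genes, 0.00 for the TCA cycle, 0.03 for glycolysis, 0.13 for the pentose phosphate pathway and 0.05 for fatty acid oxidation. Ldha was slightly higher in galactose at 620.4 against 524 CPM (ratio 1.18, 1.09 to 1.29), and Tpi1, also of the glycolysis list, was slightly lower (ratio 0.702, 0.529 to 0.931). Pdp1 and Pdp2, phosphatases that activate pyruvate dehydrogenase, had ratios of 0.476 (0.257 to 0.859) and 0.511 (0.283 to 0.903) from 19 and 21 counts in galactose, and Pdk4 had a ratio of 0.911 (0.766 to 1.08). In the Leloir pathway, Galk1 had 27.0 against 23.6 CPM (ratio 1.14, 0.749 to 1.76), with all 5 members neither (median 0.19). For histone acetylation, Acly had 80.1 against 76.1 CPM (ratio 1.05, 0.831 to 1.33) and Sirt1 108 against 101 CPM (1.06, 0.869 to 1.31). Kat5 had a ratio of 1.64 (1.17 to 2.32), while the acetyltransferase list had a median of 0.01 and the deacetylase and sirtuin list of 0.11. Txnip, which rises with glucose phosphates, had 51.6 against 54.8 CPM (ratio 0.942, 0.707 to 1.26).

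Myogenic markers stood close together in these media. Pax7 had 66.3 CPM in galactose and 54.8 in low glucose (ratio 1.21, 0.924 to 1.59), Myf5 had 366 and 370 CPM, Myod1 871 and 801 CPM (ratio 1.09, 1.01 to 1.17) and Vcam1 50.1 and 51.3 CPM. Medians were -0.03 for quiescence markers, -0.06 for myoblast markers, -0.08 for differentiation, -0.18 for Notch signalling and 0.08 for collagens. They were -0.06 for immediate early genes, -0.02 for the integrated stress response, 0.01 for the unfolded protein response, 0.04 for p53, -0.08 for interferon, 0.02 for autophagy and 0.07 for fatty acid synthesis. The means of the mitochondrially encoded (-0.02), acetyltransferase (-0.02) and myoblast (0.03) lists differed in sign from their medians. Hk2 had 8 counts in galactose, 4 in low glucose, none in high glucose and 2 in freshly isolated cells.

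**Figure D3:**
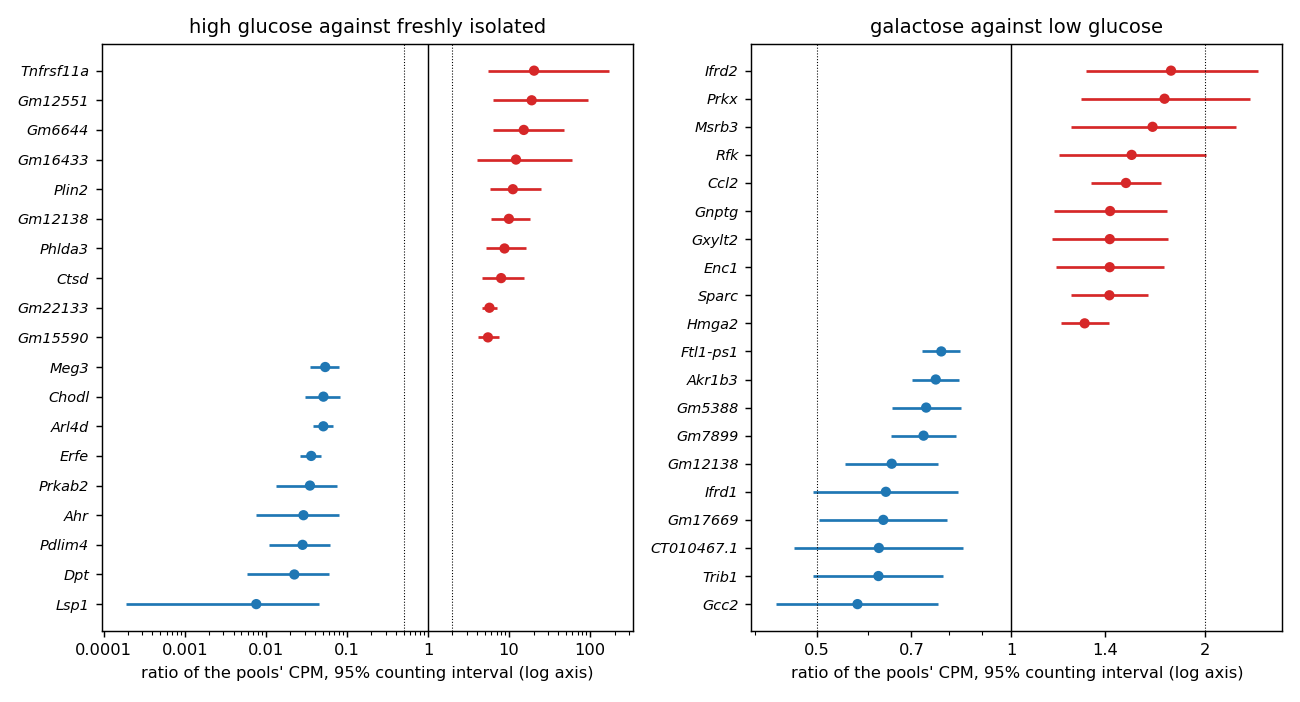
Ratio of the CPM of the pools (log axis) for higher and lower genes that the naming rule picked in each comparison within a plate (not all picked genes are drawn), with exact 95% counting intervals and dotted lines at 2-fold. Ratios reached 20.3 for Tnfrsf11a after culture and 1.77 for Ifrd2 in galactose.

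The comparison of low glucose with high glucose addresses the glucose concentration of the medium, but the conditions lay on different plates, so plate and medium cannot be separated in any value. Ass1, which makes argininosuccinate for arginine synthesis, had 111 CPM in low glucose on plate 2 and 28.2 in high glucose on plate 1 (ratio 3.95, 2.60 to 6.26). Lasp1, an actin-binding protein, had 366 against 144 CPM (ratio 2.54, 2.09 to 3.09). Ccnd1 had 205 against 98.0 CPM (ratio 2.09, 1.65 to 2.68) and Ldha 524 against 377 CPM (ratio 1.39, 1.22 to 1.58). Txnip was lower at 54.8 against 84.5 CPM (ratio 0.648, 0.474 to 0.890), as were Spry1 at 66.3 against 128 CPM (ratio 0.516, 0.395 to 0.675) and Gpx3 at 94.6 against 386 CPM (ratio 0.245, 0.202 to 0.296). Timp3 had 18 counts against 83 (ratio 0.111, 0.0627 to 0.186). Of the smooth muscle and pericyte list, Tagln had 4 counts against 36 (ratio 0.0569, 0.0147 to 0.159) and Acta2 a ratio of 0.384 (0.296 to 0.496). Pax7 had 54.8 and 56.3 CPM (ratio 0.972, 0.683 to 1.398). Acly had a ratio of 1.27 (0.920 to 1.79), Sirt1 of 0.812 (0.636 to 1.04), and Crebbp, a histone acetyltransferase, of 0.600 (0.504 to 0.714).

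Of the nuclear-encoded oxidative phosphorylation list, 19 of 60 members were higher in low than in high glucose, across plates, and 41 were neither (median log2 ratio 0.42), as with Cox6b1 (ratio 2.21, 1.72 to 2.86) and Atp5g3 (2.04, 1.71 to 2.43). Ribosomal protein genes had a median of 0.32, with 12 of 80 higher and 68 neither. Immediate early genes were lower, with 14 of 27 lower, 1 higher and 12 neither (median -0.60), as with Hspa1b (0.276, 0.242 to 0.314) and Fosb (0.256, 0.158 to 0.406). Quiescence markers had 5 of 13 lower and 8 neither (median -0.63), as with Fgfr4 (0.213, 0.0910 to 0.463). The p53 list had 2 of 15 higher, 2 lower and 11 neither (median -0.39), with Mdm2 at 0.678 (0.631 to 0.728). The pentose phosphate median was 0.41 with G6pdx at 1.64 (1.30 to 2.08), and the TCA cycle median was 0.26. Tnnt2, a troponin, had 58 counts in low glucose and 1 in high glucose (ratio 29.7, 5.12 to 1192). Of 4067 genes, 54 had a ratio of at least 2 and 70 a ratio of at least 2 in the other direction (43.5% higher). The share was 65.3% with TMM factors and 64.1% with median-of-ratios factors, which shift the all-gene median by 0.12 and 0.11, 33.3% with a total over protein-coding genes and 6.85% with spike-in scaling, which shifts it by -0.26.

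Galactose was also set against high glucose, again on different plates, so that plate and medium cannot be separated in these values either. Ass1 had 120.4 CPM in galactose on plate 2 and 28.2 in high glucose on plate 1 (ratio 4.27, 2.83 to 6.73), S100a6 had 268 against 84.5 CPM (ratio 3.17, 2.49 to 4.10) and Hmga2 673 against 261 CPM (ratio 2.57, 2.24 to 2.97). Ccnd1 had 242 against 98.0 CPM (ratio 2.47, 1.964 to 3.14) and Ldha 620.4 against 377 CPM (ratio 1.64, 1.46 to 1.86). Lower in galactose were Hspa9 (16.7 against 101 CPM, ratio 0.165, 0.108 to 0.247), Pim1 (35.4 against 162 CPM, ratio 0.218, 0.162 to 0.291) and Txnip (51.6 against 84.5 CPM, ratio 0.610, 0.450 to 0.832). The pseudogene Hspa9-ps1 also held counts, with a mean over the high glucose and freshly isolated pools of 144 CPM against 61.3 for Hspa9. The ratio of Hspa9 is uncertain, since how reads shared between these copies were counted is not given. Pax7 had a ratio of 1.18 (0.845 to 1.66).

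Oxidative phosphorylation genes had a median log2 ratio of 0.37 for galactose against high glucose, across plates, with 17 of 61 higher and 44 neither, as with Ndufs4 (ratio 3.49, 1.67 to 8.42). The pentose phosphate median was 0.56, with Taldo1 at 1.68 (1.36 to 2.09), the S phase median 0.36, with Pcna at 1.45 (1.24 to 1.695), and the ribosomal median 0.23. The acetyl-CoA median was 0.54 with 2 of 4 members higher, Acat1 at 2.53 (1.45 to 4.71) and Slc25a1 at 1.60 (1.11 to 2.37). Immediate early genes had a median of -0.50 with 13 of 27 lower, 2 higher and 12 neither, and quiescence markers one of -0.49 with 3 of 13 lower and 10 neither. Of 4096 genes, 74 had a ratio of at least 2 and 113 a ratio of at least 2 in the other direction (39.6% higher), against 62.8% with TMM factors, 66.0% with median-of-ratios factors, 52.4% with thinned cells, 24.6% with a total over protein-coding genes and 10.3% with spike-in scaling. These scalings shift the all-gene median by 0.12 for TMM, 0.14 for median-of-ratios and -0.22 for spike-ins.

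**Figure D4:**
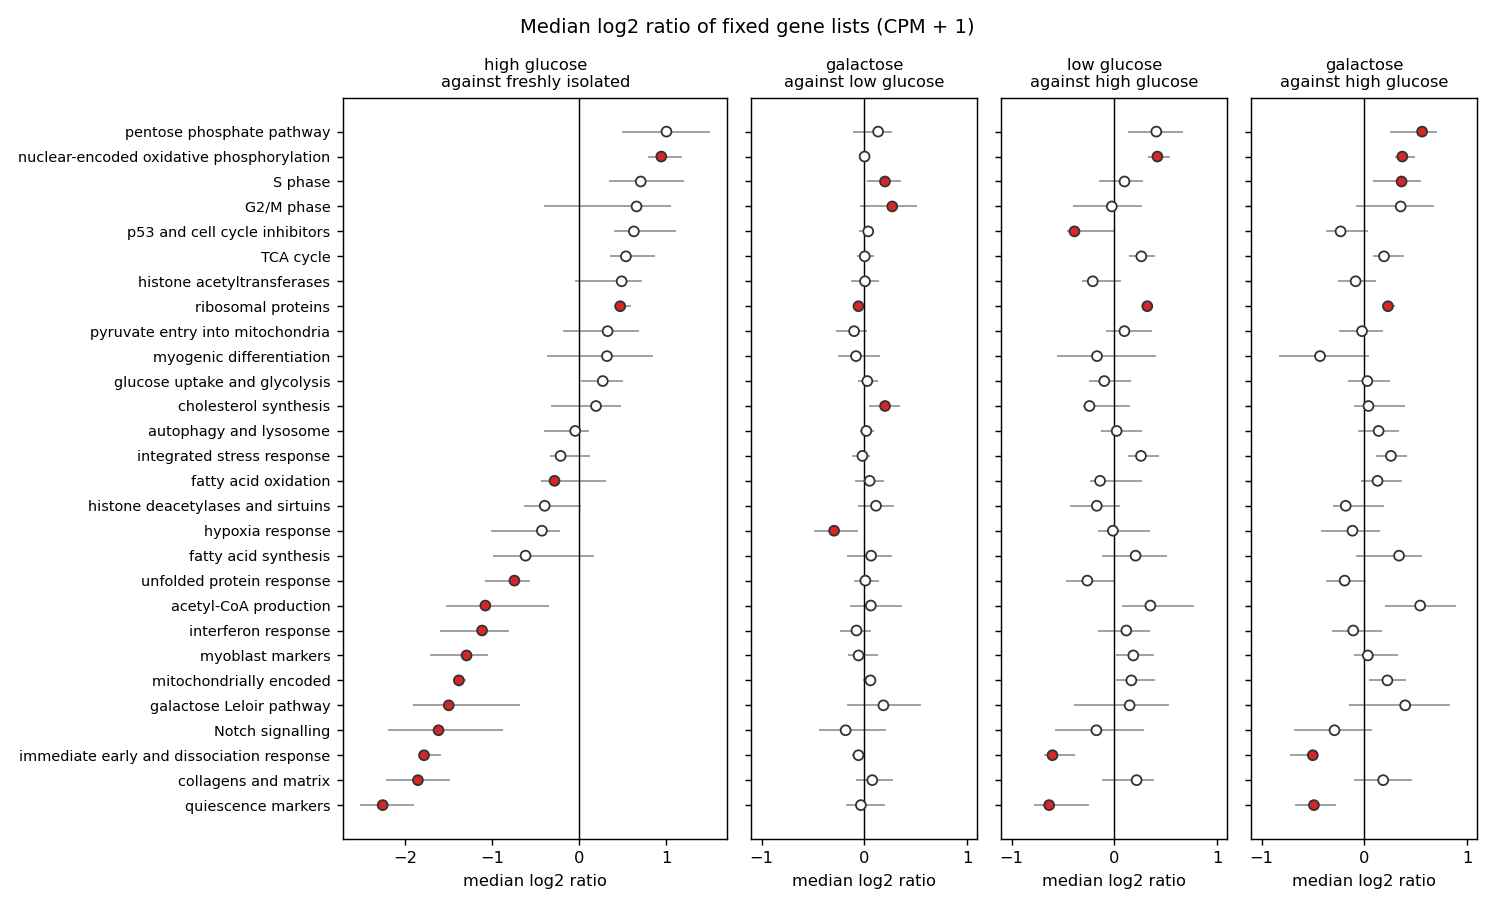
Median log2 ratio of fixed gene lists in the 4 comparisons, with lists as lines and bars for 95% intervals of the median over Poisson draws of the counts. Red points lie outside the central 95% of random lists matched on expression. Lists of other cell types are not drawn. After culture the medians of the lists drawn ran from -2.26 for quiescence markers to 1.01 for the pentose phosphate pathway. The 2 panels on the right compare different plates.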

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

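Spike-in scaling and the total over protein-coding genes were chosen after the data were seen. Over all results and settings, 1318 list medians stayed within their counting interval, 163 moved beyond it and 10 reversed. Of the named genes, 2364 values stayed, 233 moved and 3 reversed, and of the main values 80 stayed and 34 moved. Of the shares of cells, which follow depth by construction, 54 moved with the thinning depth and 18 stayed. Reversed counts a change of sign only for medians outside the central 95% of random lists and for genes whose interval lay wholly beyond 1.5-fold. A further 111 list medians and 67 gene values that did not meet this changed sign and are counted as stayed or moved. Some lists, such as G2/M at the higher list minimum, had too few members for a value. The cause of a difference was not tested except where the construction is named here.

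Each setting is followed by numbers of genes with a ratio of at least 2, higher then lower. The lower expression minimum admits genes with few counts by construction, and gave 2292 and 1160 genes for high glucose against freshly isolated cells, 22 and 21 for galactose against low glucose, 250 and 404 for low against high glucose, and 313 and 483 for galactose against high glucose. Thinning to 1000 counts leaves fewer counts by construction and gave 186 and 186 for galactose against low glucose, 335 and 318 for low against high glucose, and 377 and 343 for galactose against high glucose. It reversed the fatty acid oxidation median after culture (0.080) and the cholesterol median in galactose against low glucose (-0.011). TMM factors gave 94 higher genes for low against high glucose and 120 and 71 for galactose against high glucose, and median-of-ratios factors gave 91, and 132 and 68. A pseudocount of 10 CPM, which shrinks ratios by construction, gave 25 and 46 for low and 48 and 74 for galactose against high glucose.

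Spike-in scaling gave 2928 and 63 genes for high glucose against freshly isolated cells, 17 and 231 for low against high glucose, and 30 and 260 for galactose against high glucose. It raises every ratio of high glucose to freshly isolated cells by 1.62 on the log2 scale by construction, before the pseudocount. With this scaling medians so defined reversed for the myoblast (0.52), Leloir (0.087), mitochondrially encoded (0.22), fatty acid oxidation (1.33), acetyl-CoA (0.49), unfolded protein (0.87), Notch (0.24) and interferon (0.48) lists, and so did the log2 ratios of H2-K1 (0.092), mt-Cytb (0.24) and Ugp2 (0.015). The medians of the hypoxia (1.14), integrated stress (1.36), deacetylase (1.20), fatty acid synthesis (0.95) and autophagy (1.56) lists also became positive, from negative medians within the central 95%. The list minimum was applied again, which changed the members of some lists. With the members kept, the myoblast median was 0.30 and the Notch median, at -0.025, did not reverse. A total over protein-coding genes gave 1161 higher genes after culture, 1 lower gene in galactose against low glucose, and 128 and 224 lower genes for low and galactose against high glucose. The freshly isolated pool held 284109 counts, the fewest of the 4 pools, which widens its intervals.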

Other observations

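Of the tests in this part, those on total RNA and on pseudogene families were chosen or worded after the result was seen. The test on depth was chosen after the pattern was seen, in place of thinning, and its limits were set before its value was computed. Thinning weights cells equally but leaves the expected proportions within each cell unchanged, and so decides nothing about depth. For the test on other cell types the interval it was judged by was chosen after its value was seen, in place of a minimum of 20 wells that would have left it undecided.

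Freshly isolated cells stood apart from the others far more than galactose and low glucose cells did from each other. Among the 10 nearest neighbours of each freshly isolated cell, after thinning, 96.4% were freshly isolated. Among those of low glucose cells 41.6% were low glucose and 45.2% galactose cells, and among those of galactose cells 48.1% were galactose and 43.1% low glucose cells. High glucose cells, on the other plate, had 53.7% of neighbours from their own condition. Gm42418, a transcript overlapping a ribosomal RNA repeat, took 49052 CPM in freshly isolated, 37565 in high glucose, 23745 in low glucose and 21670 in galactose cells.

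Immediate early genes and Myod1 were higher in CPM in freshly isolated cells, and the cells' smaller RNA content is a candidate explanation, since a fixed amount of a transcript makes up more of a small total. Per spike-in count, 58.6% of 29 members (Myod1 included) had an interval within reach of 1.5-fold around 1, while 6 lay below and 6 above, which is between the limits set for the test, so total RNA cannot be told apart from regulation for the group. The same share was 90.9% for mitochondrially encoded genes, 80% for collagens and matrix and 75% for myoblast markers. It was 71.4% for the Notch list and 70.6% for quiescence markers. No limits were set for these lists. Nr4a1 and Hspa1a stayed lower in high glucose per spike-in count (ratios 0.160 and 0.253), and Klf6 and Ier3 were higher (2.94 and 3.65). In the 15 freshly isolated wells without a count of any marker of another cell type the median of the immediate early list was -1.48 (95% interval -1.69 to -0.98). It was -1.78 in all wells, so the pattern did not rest on wells with such counts, though few wells lie behind this. Col3a1, 1 of the markers, had a count in 72 of 102 freshly isolated wells and in 61.9% of high glucose cells. The split may therefore not separate wells with other cells from wells without. A shallow well without a count of these 18 markers, only 1 of them immune, can still hold another cell. Cells of another type are therefore not excluded. A response to isolation remains open and was not tested.

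The high glucose pool stood apart from both pools of the other plate, and medium and plate cannot be told apart there. Spike-in species, the same RNA in all wells, spread between plates beyond counting error by 0.324 on the log2 scale against 0.399 for genes of similar counts, and by 0.117 and 0.0797 within plates. The upper end of the interval, 0.531, exceeds the value for genes, so differences in library making between the plates may account for much of the pattern. For depth, only differences between wells of 1 plate could be examined. The 124 genes with a ratio of at least 2 in either direction between low and high glucose had a median log2 ratio, signed as between these pools, of 1.15. Between the deeper and the shallower low glucose wells, which differed 2.45-fold in median depth against 1.98-fold between the pools, it was 0.15 (95% counting interval 0.08 to 0.24). Depth differences of this kind are thus argued against as the whole of the pattern. The split follows gene counts, which also vary with the RNA of each cell. Median spike-in counts per well were 259.5 in low glucose and 131 in high glucose, so an effect of depth between whole plates is not excluded. The effect of glucose stays open.

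Pseudogenes were 33.8% of the genes at least 2-fold higher in high glucose than in freshly isolated cells, 5.93% of the lower and 18.6% of all compared. In low glucose against high glucose they were 48.6% of the lower, 7.41% of the higher and 19.9% of all compared genes, and in galactose against high glucose 53.1%, 5.41% and 19.8%. Reads shared between copies of a gene are a candidate explanation. Within 67 families of a gene and its pseudogenes, 47 of them ribosomal, the median SD of log2 ratios was 0.200 against 0.447 after members were shuffled among families, and none of 10000 shuffles was lower. Copies of a gene thus moved together, which shared reads predict. This does not explain why pseudogenes were more frequent among the genes that differed at least 2-fold. Families were built from shared gene names, so Gm6644, Gm12551 and Gm12138 were not in them. Transcription of the pseudogenes themselves was not tested.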
